A study of Mus musculus with 6 samples.

How the data were processed

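The series measured RNA of single CD45+ cells, sorted by flow cytometry from orthotopic 4T1 tumours, in 6 libraries: 1 of sgNC and 1 of sgRNA tumours on each of days 6, 8 and 10. Per the labels' protocols, tumours were digested with collagenases, red cells were lysed, and libraries followed the 10x 3' version 2 protocol. For each library the authors deposited a matrix of counts, the number of unique molecular identifiers (UMIs) per gene and cell barcode, with no normalization. Per the submitters' processing notes, Cell Ranger 2.1.1 and mm10 were used, whereas per the file headers the matrices came from Cell Ranger 4.0.0. The 55450 gene identifiers and symbols equalled those of GENCODE vM21 on GRCm38, which gave the gene positions. The files held called cells only, so empty droplets were not at hand to measure free RNA, and its share was bounded from the classes instead.

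Depth per library was 110503845 UMIs in 11732 barcodes (sgNC, day 6), 116460040 in 10522 (sgRNA, day 6), 150997145 in 14081 (sgNC, day 8), 103065573 in 9319 (sgRNA, day 8), 88269217 in 11502 (sgNC, day 10) and 74898722 in 9548 (sgRNA, day 10). Median UMIs per barcode were 4605, 7178, 7284, 6846, 5613.5 and 5821 in the same order. Barcodes with at least 200 genes and under 10% mitochondrial UMIs were kept. Scrublet, as in scanpy 1.11.5, was run per library with an expected rate of 0.06, and cells with a score over 0.2 were left out. The automatic Scrublet limit removed hardly any cells in 3 libraries, so the limit of 0.2 was set after the data were seen. Cells used numbered 11197 and 9878 on day 6, 13253 and 8740 on day 8, and 10706 and 9046 on day 10 in sgNC and sgRNA.

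Counts were scaled per cell and log transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1 (igraph 0.11.9, seed 1) gave 30 clusters, and 37 after clusters led by markers of another class were divided at resolution 0.5. Clusters were named from 22 marker lists written before the data were examined. A name needed at least 3 markers at least 1 log2 above the median cluster, each in at least 10% of cells, with a prior of 5 CPM, and the list with the highest mean score gave it. Clusters with over 40% doublets, with few UMIs and no marker among their 10 leading genes, or with more markers of another class among those 10 were left unnamed. Clusters with Mki67 or Top2a in over 85% of cells were called cycling. The naming thresholds, the division of clusters and the limit of 85% were set after the data were seen. Names end in "-like" because they rest on RNA alone, and 16 classes were named. Cluster 2 was nearest to macrophages (15 of 18 markers), stayed unnamed as 1 marker of type 2 innate lymphoid cells and 0 of macrophages were among its leading genes, and was compared by its number. The largest of the other unnamed clusters, with Hbb-bs, Retnlg and Ccr3 among its leading genes, held 16.6% of the sgNC and 4.13% of the sgRNA library on day 6, 3.89% and 4.73% on day 8, and 2.37% and 3.32% on day 10.

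For each class with at least 30 cells in every library UMIs were summed per library, which left 14 classes for gene tests. Low counts were removed with filterByExpr, libraries were scaled by TMM, and edgeR 4.0.16 quasi-likelihood tests in R 4.3.3 compared sgRNA with sgNC with day as a block, on 2 residual degrees of freedom per gene with spread pooled over genes. Genes with a Benjamini-Hochberg adjusted p under 0.05 within their class were called. The numbers 1, 2 and 3 of the libraries stand for days 6, 8 and 10 by the labels, so each sgRNA library was paired with the sgNC library of its day. The pairing was checked by correlating the libraries of a day after the mean of each treatment was removed: 40 of 42 values were over 0.1, from 0.0633 to 0.511 with a median of 0.270. Slopes per day were fitted with treatment and day as a number (3 residual degrees of freedom), and the difference of slopes with a treatment by day term (2). Shares were tested with edgeR on cell counts against the number of cells used, adjusted over 17 classes, and with exact permutation over the 10 splits of 6 libraries into 3 and 3, which cannot give a p under 0.1. Single days held 1 library per treatment and were given as values with exact 95% binomial intervals. CPM are means over libraries of a treatment with the SD.

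The 21 gene lists of 9 to 41 genes, written from general knowledge before the data were examined, were tested with camera in limma 3.58.1 at the preset correlation of 0.01 and with an estimated correlation, for lists with at least 5 members measured, adjusted over all pairs of list and class. They were type I interferon response, interferon gamma response, MHC class I and class II presentation, cytotoxic effector, inhibitory receptor and exhaustion, naive and memory T, T cell activation and costimulation, alternative macrophage activation, inflammatory cytokine and chemokine, lipid-associated macrophage, hypoxia and glycolysis, oxidative phosphorylation, S phase, G2 and M phase, immediate early and dissociation stress, unfolded protein response, apoptosis and p53, granulocytic suppressor, mitochondrially encoded, and PD-1 and CD28 ligand and receptor. Of the listed symbols, 2 were in no file. Member counts were also adjusted over the list alone.

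Genes were named by a rule fixed before the data were examined. Per class these were the 5 largest rises and 5 largest falls among genes past the threshold with the same sign on all 3 days and a mean log2 CPM of at least 4, without ribosomal protein, mitochondrial, predicted and receptor segment genes, or the 4 smallest p where fewer than 4 passed. Members of the lists past the threshold were eligible, and 2 to 4 per list were chosen as examples after the data were seen, as were the genes in the T cell plot. Of these examples, 2 are not reported here. Cd28, Cd274, Pdcd1, Ctla4, Cd80, Cd86, Ifng, Gzmb and Prf1 were given whatever their values. Over days the 4 largest slopes in each direction were named, without the minimum on CPM.

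The procedure was tested on simulated data made from these libraries with 100 genes per class changed by 2-fold and 100 by 4-fold. edgeR recovered 71% and 92% of them in CD4 T-like, 31% and 87% in CD8 T-like, 72% and 90% in NK-like, 54% and 84% in macrophage-like and 76% and 97% in regulatory T-like cells, with 0 of the wrong sign and 15, 4, 14, 17 and 13 false calls. Slopes of 0.5 log2 per day were recovered in 85.5% (CD4 T-like) and 84.5% (NK-like) of cases.

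Alternatives chosen before the data were examined were: doublets kept, at least 500 genes per cell, under 5% mitochondrial UMIs, Leiden resolution 2, an equal number of cells per library, no block, DESeq2 size factors, the DESeq2 1.42.0 Wald test, no filter on low counts, genes under 5% of their top class left out, each day or library left out, TMM factors over classes, shares without neutrophils, and an estimated correlation. The 5 alternatives of an estimated correlation for marker lists, of leaving out cycling clusters, of leaving out CD8 T-like cells with a Mki67 or Top2a UMI, of immune classes alone as the denominator and of leaving out unnamed clusters from it were added after the data were seen. Preliminary fits had been looked at before the tests of technical explanations were written down, so the patterns were known and the values of those tests were not, except for CD4 T-like against other lymphoid cells. For Cd28 and Ptprc in single cells, UMIs were also thinned to 3000 per cell, which left out shallower cells (319 epithelial or tumour-like, 342 fibroblast or pericyte-like, 1041 macrophage-like, 460 monocyte-like and 784 CD4 T-like). Other tools were python 3.11.15, scipy 1.17.1, scikit-learn 1.9.0, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Mast or basophil-like, endothelial-like and epithelial or tumour-like cells had too few cells in some libraries and were not tested for genes.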

Results

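The series held 6 single-cell 3' libraries of CD45+ cells sorted from orthotopic 4T1 mammary tumours in BALB/c mice. On each of days 6, 8 and 10 there was 1 library from tumours labelled sgNC, the control, and 1 from tumours labelled sgRNA. The labels named a genome-wide knockout library as the source of the guides and did not name the gene removed in the sgRNA tumours. After filtering, 62820 cells remained, and 16 classes were named from marker genes: CD4, CD8, regulatory and gamma delta T-like, NK-like, 4 dendritic cell (DC) classes, macrophage-like, monocyte-like, neutrophil-like, mast or basophil-like, and endothelial-like, epithelial or tumour-like and fibroblast or pericyte-like cells. A group of myeloid cells with Mmp12, Nos2, Inhba, Vegfa and Hmox1 among its leading genes was kept as cluster 2. No label states that the libraries came from separate animals, so each p-value measures only the spread between these libraries, which may be technical.

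CD4 T-like cells made up a larger part of the sorted CD45+ cells in sgRNA tumours on each day, and macrophage-like cells a smaller part on each day. CD4 T-like cells were 3.73% (95% exact binomial interval 3.39 to 4.10, counting error only) of the sgNC library and 6.81% (6.32 to 7.33) of the sgRNA library on day 6. On day 8 CD4 T-like cells were 5.51% (5.13 to 5.91) and 13.6% (12.9 to 14.3), and on day 10 they were 4.66% (4.27 to 5.08) and 13.9% (13.2 to 14.6). The mean CD4 T-like share was 4.63 ± 0.888% (SD, n = 3) in sgNC and 11.4 ± 4.00% (SD, n = 3) in sgRNA, a log2 fold change of 1.25 with an edgeR adjusted p = 0.245. Macrophage-like cells averaged 22.3 ± 2.55% (SD, n = 3) in sgNC and 14.9 ± 3.94% (SD, n = 3) in sgRNA, a log2 fold change of -0.61 with an edgeR adjusted p = 0.413. Of the 17 classes, 0 passed the adjusted threshold in edgeR, and 2 had an unadjusted p under 0.05: CD4 T-like (0.0144) and endothelial-like (0.0351) cells. The exact permutation p was 0.1 for CD4 T-like and for macrophage-like cells, the smallest value 10 splits can give. With immune classes alone as the denominator, an alternative added after the data were seen, CD4 T-like cells gave 1.29 with an edgeR adjusted p = 0.0430, against 0.0739 to 0.674 over the other edgeR alternatives. Cross-presenting cDC1-like cells (0.882% and 1.77%) and fibroblast or pericyte-like cells (1.48% and 2.58%) were also more frequent in sgRNA on all 3 days, at log2 fold changes of 0.89 and 0.63. Mast or basophil-like cells (2.20% and 1.52%) were less frequent on all 3 days, at -0.73. Regulatory T-like cells averaged 2.62% and 4.16%, CD8 T-like cells 4.99% and 6.22%, cDC2-like cells 2.31% and 3.11%, plasmacytoid DC-like cells 0.879% and 1.15% and monocyte-like cells 10.4% and 14.8% in sgNC and sgRNA. Neutrophil-like cells averaged 20.1% and 15.9%, NK-like cells 4.90% and 4.29%, gamma delta T-like cells 0.852% and 0.927%, mature DC-like cells 0.825% and 0.696%, cluster 2 8.19% and 6.01%, and epithelial or tumour-like cells 2.93% and 3.87%.

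**Figure D1:**
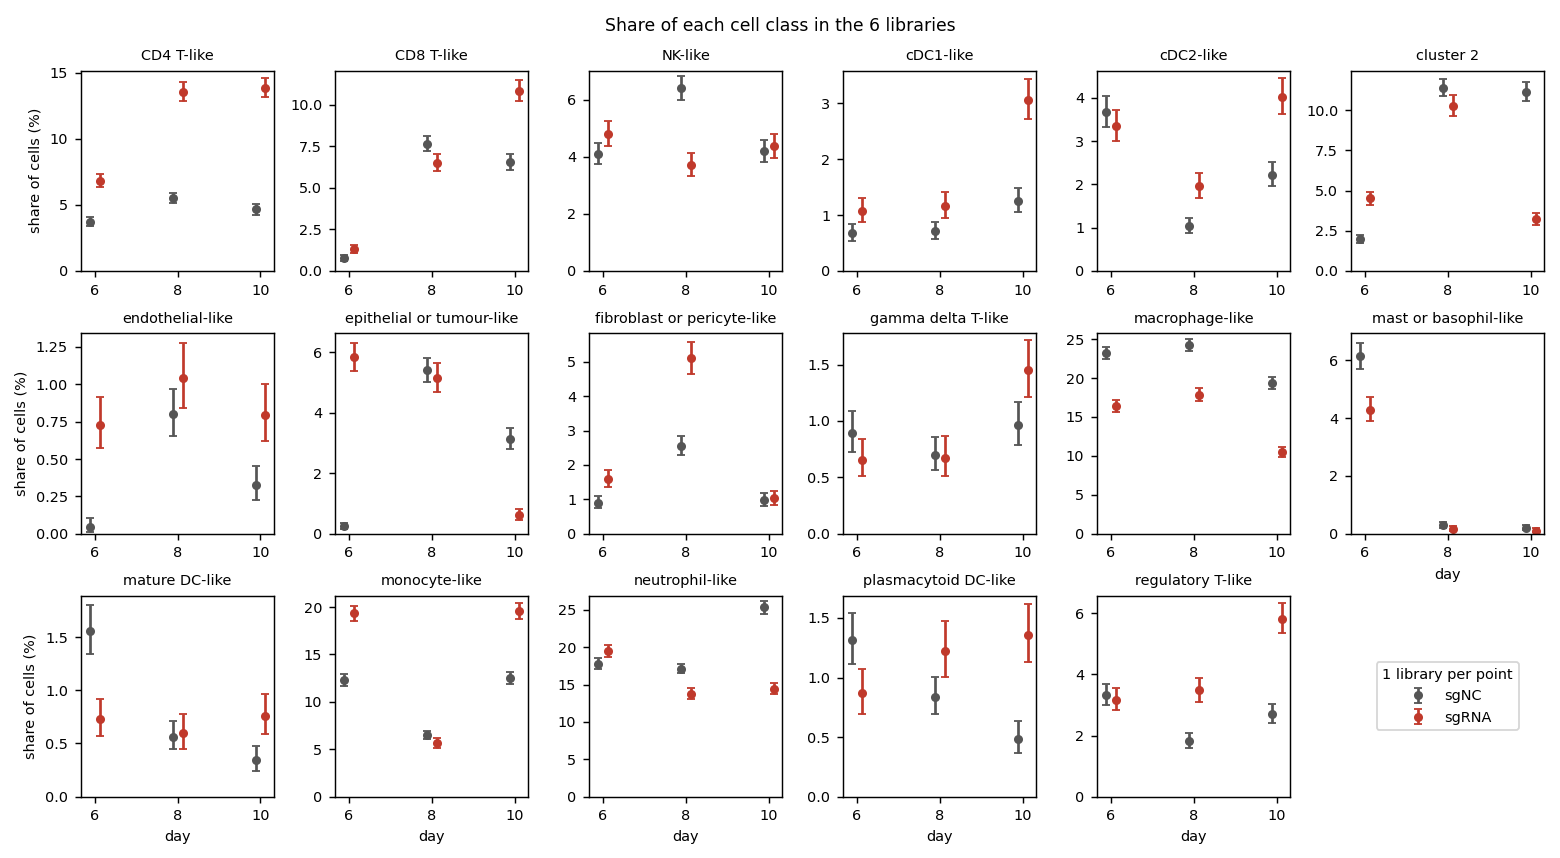
Share of each cell class among the sorted CD45+ cells of each library by day. Bars are exact binomial intervals and show counting error only.

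Within the macrophage-like class, cells of the cluster led by Adamdec1, Mmp13 and C1q genes made up 39.3% in sgNC and 7.52% in sgRNA on day 6, 44.2% and 6.84% on day 8, and 5.39% and 4.97% on day 10. Macrophage-like cells of the cluster with Ccl5, Pf4 and Apoe were 25.0% in sgNC and 41.3% in sgRNA over the days. The cluster with Cbr2, Folr2 and Selenop held 1.08% and 23.2% of macrophage-like cells on day 6 and 12.9% and 46.0% on day 8, and on day 10 it held 55.2% in sgNC and 41.4% in sgRNA, the other way. The monocyte-like class was split between a cluster with Dmkn, Ccl24 and Tgm2 (51.8% in sgNC and 20.7% in sgRNA) and a cluster with Ly6c2 and Adgre4 (48.2% and 79.3%). Cycling clusters held 17.9% and 8.58% of CD8 T-like cells in sgNC and sgRNA. At Leiden resolution 2, a cluster named type 2 innate lymphoid-like (5 of 10 markers), led by Il13, Ccl1, Il5, Il2, Ifng and Cd4, held 39.7% and 17.0% of CD4 T-like cells. A cluster led by Gzmg, Gzmd and Gzme held 11.9% and 1.93% of NK-like cells. Shares without a day pool 3 days, and all are descriptive. The macrophage, monocyte, CD4, CD8 and NK comparisons thus weigh different clusters in the 2 treatments. Clusters left without a name held 17.3% of the sgNC and 4.95% of the sgRNA library on day 6, 6.40% and 8.10% on day 8, and 3.61% and 4.19% on day 10, so the day 6 shares of sgNC rest on fewer named cells.

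Genes were compared within 14 classes between sgRNA and sgNC with day as a block. Of 160579 tests of a gene in a class, 407 were higher and 744 lower in sgRNA by edgeR, with NK-like (122 and 142), CD4 T-like (74 and 145), cluster 2 (69 and 140), CD8 T-like (88 and 68) and cDC2-like (21 and 115) cells holding most. DESeq2 gave 527 higher and 990 lower. With day left out of the model, edgeR called 25 (8 higher and 17 lower). Leaving out 1 day at a time gave 1164 to 2506. Granzyme B (Gzmb) was negative in all 14 classes and fell past the threshold in 7 of them. Whether the fall differed between classes was not tested. The interferon-induced membrane gene Ifitm1 fell in 7 classes, the collagenase gene Mmp13 in 8, Gzmc in 6, and the chemokine gene Ccl24, the lectin gene Lgals3, the secreted phosphoprotein gene Spp1 and the glycolysis gene Tpi1 in 5 each. Of these calls 2 of 7 for Gzmb, 2 of 7 for Ifitm1, 4 of 8 for Mmp13, 4 of 6 for Gzmc, 2 of 5 for Ccl24 and 1 of 5 for Spp1 were at under 5% of the level in the top class. The fatty acid binding gene Fabp4 rose in 5 classes, and in all 5 its level was under 5% of that in its top class.

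**Figure D2:**
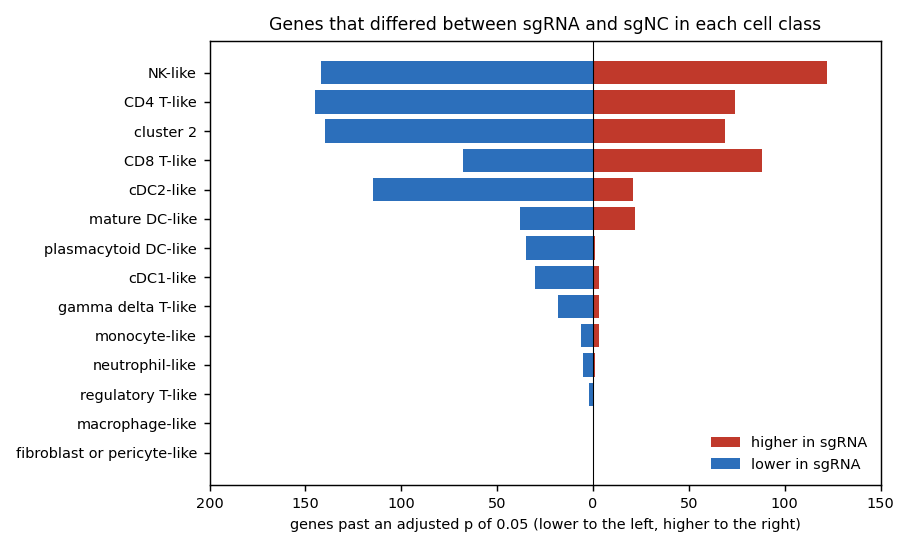
Genes higher and lower in sgRNA than in sgNC tumours within each cell class by edgeR.

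In CD4 T-like cells of sgRNA tumours Il5, Il4, Pdcd1 and some other inhibitory receptor genes fell, and Cxcr3 and a few naive and memory T cell genes rose. Il5, which drives eosinophil production, fell most, from 263 ± 161 (SD, n = 3) to 25.6 ± 23.7 (SD, n = 3) counts scaled to the library total (CPM), a log2 fold change of -3.50 with an edgeR adjusted p = 0.000253. Il4, the other main type 2 cytokine, fell by 2.20 log2 (edgeR adjusted p = 0.0186), and without day 6 its adjusted p was 0.0750. The enkephalin precursor Penk fell by 2.25 log2 (edgeR adjusted p = 0.000253), from 255 to 58.2 CPM. The serine protease inhibitor gene Serpinb9b fell by 2.99 log2 and the receptor modifier gene Ramp3 by 1.73 log2, with edgeR adjusted p = 0.00233 and 0.0186. Cxcr3, the receptor for the interferon-induced chemokines Cxcl9 and Cxcl10, rose from 31.2 to 72.7 CPM (log2 fold change 1.28, edgeR adjusted p = 0.0116). The memory surface gene Ly6c2 (1.31), the lysophosphatidic acid receptor gene Lpar6 (1.10), the sialyltransferase gene St3gal6 (1.10) and the neuropeptide receptor gene Vipr1 (0.97) also rose, with edgeR adjusted p from 0.0116 to 0.0296.

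Of 22 inhibitory receptor and exhaustion genes in CD4 T-like cells, 0 rose and 8 fell, and 0 rose and 15 fell when adjusted over the list alone. The camera test of that list gave an adjusted p = 1.27e-14 with the preset correlation and adjusted p = 0.53 with an estimated correlation. Pdcd1, which encodes PD-1, fell from 164 ± 16.9 (SD, n = 3) to 93.4 ± 27.2 (SD, n = 3) CPM, a log2 fold change of -0.83 (edgeR adjusted p = 0.0242). Havcr2 (-1.43), which encodes TIM-3, Lag3 (-1.19) and Ctla4 (-0.61) fell as well, with edgeR adjusted p = 0.0222, 0.0359 and 0.0427. The costimulatory receptor gene Tnfrsf9, which marks recent antigen contact, fell from 748 to 293 CPM, and the IL-2 receptor gene Il2ra fell by 0.78 log2 (edgeR adjusted p = 0.0186 and 0.0151). Among 17 naive and memory T cell genes 4 rose and 1 fell, and 8 rose and 1 fell adjusted over the list alone (camera adjusted p = 6.72e-06, and 0.53 with an estimated correlation). The transcription factor gene Tcf7 (0.64), the receptor gene Slamf6 (0.60), the egress receptor gene S1pr1 (0.73) and the quiescence factor gene Klf3 (0.56) rose, with edgeR adjusted p from 0.0222 to 0.0348. Of 27 hypoxia and glycolysis genes 0 rose and 3 fell, and 0 rose and 16 fell adjusted over the list alone (camera adjusted p = 3.50e-12, and 0.53 with an estimated correlation). The glycolysis genes Tpi1 (-0.57) and Pkm (-0.43) passed with edgeR adjusted p = 0.0285 and 0.0443. Gzmb fell by 1.10 log2 (edgeR adjusted p = 0.0427). Ifng (-0.39, adjusted p = 0.218), Prf1 (-0.85, adjusted p = 0.0532) and Cd28 (0.18, adjusted p = 0.332) were not past the threshold in edgeR.

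DESeq2 counted 48 higher and 139 lower genes in CD4 T-like cells, and leaving out day 6, 8 or 10 left 40, 428 and 34 genes by edgeR, with Il5, Penk, Serpinb9b, Cxcr3, Ly6c2 and Tnfrsf9 past the threshold each time. Marker genes of type 2 innate lymphoid cells (median -1.20) and of mast or basophil cells (-1.82) fell within the class by camera. Markers of regulatory T cells (-0.68) and macrophages (-0.54) were lower while fibroblast markers (1.42) were higher. None of these passed with an estimated correlation. The cluster named type 2 innate lymphoid-like at resolution 2 held 44.0% and 21.1% of the class in sgNC and sgRNA on day 6, 42.5% and 22.6% on day 8, and 32.1% and 9.47% on day 10. In the CD4 T-like class of resolution 2, without that cluster, Il5 (-3.96), Penk (-2.00), Pdcd1 (-0.88) and Cxcr3 (0.95) passed in edgeR, while Il4 (-1.13, adjusted p = 0.0643) and Tcf7 (0.19, adjusted p = 0.519) did not.

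In CD8 T-like cells of sgRNA tumours granzymes and PD-1 fell and Tcf7, Slamf6, S1pr1 and Klrg1 rose. The granzyme genes Gzmc (-4.41, from 626 to 33.1 CPM), Gzmd (-3.71), Gzme (-3.73) and Gzmf (-3.58) fell most, with edgeR adjusted p from 0.000224 to 0.0319. Gzmc, Gzmd, Gzme and Gzmf are near-identical neighbours on chromosome 14, so which of them fell is uncertain, while their joint fall is not a matter of assignment. Gzmb, whose product activates caspases in target cells, fell by 1.39 log2 from 5238 ± 881 (SD, n = 3) to 2090 ± 860 (SD, n = 3) CPM (edgeR adjusted p = 0.0332). Pdcd1 fell by 1.71 log2, from 252 ± 56.9 (SD, n = 3) to 80.1 ± 44.4 (SD, n = 3) CPM (edgeR adjusted p = 0.00954). The glycine decarboxylase gene Gldc (-3.26), the neuritin gene Nrn1 (-2.56), the inhibitory receptor gene Cd244a (-1.74) and the ectonucleotidase gene Entpd1 (-0.96), which marks exhausted cells, fell with edgeR adjusted p from 0.00104 to 0.0370. Gzmm (2.43), the granzyme of resting cytotoxic cells, Klrg1 (2.35), a receptor of short-lived effector cells, the sialic acid enzyme gene Cmah (1.91) and the egress receptor gene S1pr1 (1.94) rose, with edgeR adjusted p from 0.00219 to 0.00316. The stem-like memory genes Tcf7 (1.71), Slamf6 (1.80) and Klf3 (1.87) rose with edgeR adjusted p from 0.00219 to 0.00298.

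Of 18 naive and memory T cell genes in CD8 T-like cells 6 rose and 0 fell, and 15 rose and 0 fell adjusted over the list alone (camera adjusted p = 1.72e-21, and 0.53 with an estimated correlation). Of 22 inhibitory receptor and exhaustion genes 0 rose and 4 fell, and 1 rose and 8 fell adjusted over the list alone (camera adjusted p = 2.14e-08, and 0.54 with an estimated correlation). Of 26 cytotoxic effector genes 1 rose and 5 fell, and 4 rose and 11 fell adjusted over the list alone (camera adjusted p = 7.57e-08, and 0.53 with an estimated correlation). Of 41 type I interferon response genes 5 rose and 0 fell, and 24 rose and 1 fell adjusted over the list alone (camera adjusted p = 1.40e-14, and 0.53 with an estimated correlation). The interferon response genes Ifit1bl1 (2.47), Oas3 (1.29) and Slfn5 (1.10) rose with edgeR adjusted p from 0.0160 to 0.0319, whereas Ifitm1 (-2.41) and Ifitm2 (-1.77), which also respond to interferon, fell with edgeR adjusted p = 0.000516 and 0.00104. Prf1 (-1.29, adjusted p = 0.0727), Ctla4 (-0.92, adjusted p = 0.136), Ifng (-0.13, adjusted p = 0.924) and Cd28 (0.45, adjusted p = 0.238) were not past the threshold in edgeR in CD8 T-like cells.

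DESeq2 gave 120 higher and 86 lower genes in CD8 T-like cells, against 88 and 68 by edgeR. Day 6 held 87 sgNC and 130 sgRNA CD8 T-like cells, and leaving out day 6, 8 or 10 left 4, 77 and 669 genes, with Gzmc, Gzmd and Gzme past the threshold each time. The cluster of resolution 2 led by Cd8b1 and Gzmk, with Tcf7, held 66.7% and 83.8% of CD8 T-like cells in sgNC and sgRNA on day 6, 17.9% and 52.1% on day 8, and 21.97% and 68.6% on day 10. The cluster led by Ifng held 12.6% and 3.08%, 37.3% and 37.3%, and 64.9% and 18.35% on these days, and the cycling cluster led by Gzmf 20.7% and 12.3%, 43.9% and 10.04%, and 12.55% and 12.2%. The changes of the class thus lay beside a shift between clusters. Markers of regulatory T cells (-0.89) and macrophages (-0.69) were lower and of fibroblasts (0.94), CD4 T cells (0.19) and monocytes (0.14) higher in CD8 T-like cells by camera with the preset correlation alone.

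**Figure D3:**
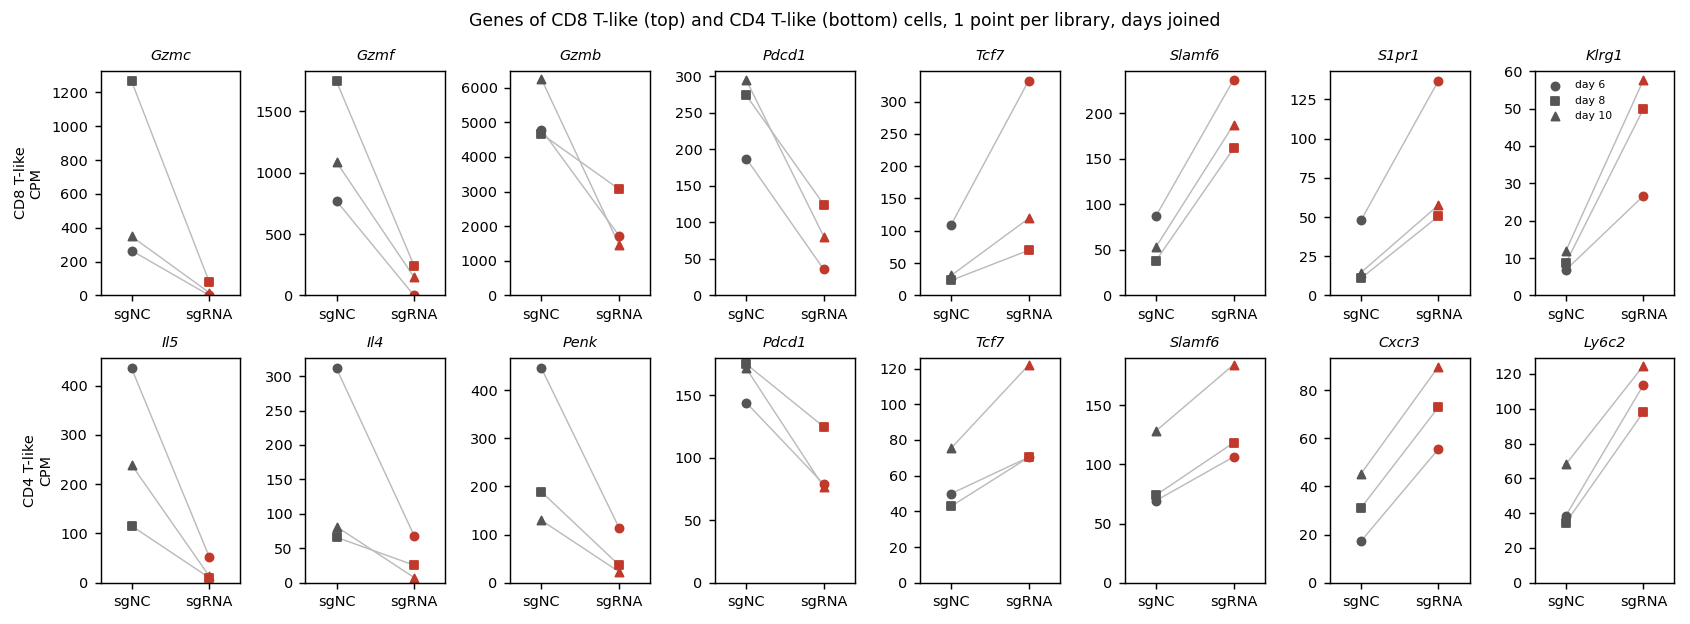
CPM of effector, cytokine, PD-1 and memory genes in CD8 T-like (top) and CD4 T-like (bottom) cells. Each point is 1 library and lines join the libraries of a day.

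NK-like cells lost granzyme, perforin and glycolysis transcripts in sgRNA tumours and gained Il7r, Cxcr3 and Klf3. Gzmb fell by 1.36 log2, from 3854 ± 966 (SD, n = 3) to 1861 ± 1232 (SD, n = 3) CPM, and the pore-forming perforin gene Prf1 by 1.06 log2, from 1710 to 948 CPM (edgeR adjusted p = 0.0354 and 0.0444). Gzmd (-3.17), Gzme (-3.14), Gzmf (-3.00) and Gzmg (-4.88) fell with edgeR adjusted p from 0.000234 to 0.0246, again as near-identical paralogs that cannot be told apart with certainty. Havcr2 fell by 1.88 log2 (edgeR adjusted p = 0.0285). The glycolysis genes Ldha (-0.68), Gapdh (-0.69) and Pgk1 (-0.66) fell with edgeR adjusted p from 0.0310 to 0.0350. The IL-7 receptor gene Il7r (1.07), a survival receptor of helper-like innate cells, Cxcr3 (1.13), Klf3 (1.09), S1pr1 (1.21), Slamf6 (1.18) and the lipid flippase gene Atp10d (1.09) rose with edgeR adjusted p from 0.00107 to 0.0317. Of 26 hypoxia and glycolysis genes 0 rose and 13 fell, and 0 rose and 19 fell adjusted over the list alone (camera adjusted p = 2.76e-18, and 0.53 with an estimated correlation). Of 26 cytotoxic effector genes 1 rose and 8 fell, and 3 rose and 11 fell adjusted over the list alone (camera adjusted p = 7.70e-08, and 0.53 with an estimated correlation). Ifng (-0.02, adjusted p = 0.956), Pdcd1 (-0.88, adjusted p = 0.132) and Cd28 (0.40, adjusted p = 0.0842) were not past the threshold in edgeR in NK-like cells.

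Of the genes past the threshold in NK-like cells, 46.2% were higher in edgeR (122 of 264) and 30.1% in DESeq2 (31 of 103). Leaving out day 6, 8 or 10 left 577, 240 and 49 genes by edgeR, with Gzmd, Gzme, Havcr2, Cxcr3 and Il7r past the threshold each time. Markers of CD4 T (0.82), CD8 T (0.44) and fibroblast (1.41) cells were higher and markers of macrophages (-0.89) and neutrophils (-0.54) lower in NK-like cells by camera, and 0 of these passed with an estimated correlation. The granzyme-led cluster of resolution 2 held 4.36% and 0.211% of NK-like cells in sgNC and sgRNA on day 6, 17.1% and 6.19% on day 8, and 9.82% and 0.506% on day 10. In the NK-like class of resolution 2, which kept that cluster, Gzmb (-1.35, adjusted p = 0.0581) and Prf1 (-1.02, adjusted p = 0.0673) no longer passed in edgeR.

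In gamma delta T-like cells of sgRNA tumours a few cytotoxic and interferon response genes fell. Gzmb fell by 2.28 log2, from 822 to 240 CPM, and the guanylate binding gene Gbp11 by 2.04 log2 (edgeR adjusted p = 0.00359 and 0.00992). Gzma (-2.29), the death ligand gene Fasl (-2.03) and Tnfrsf9 (-2.11) fell with edgeR adjusted p = 0.0453, 0.0497 and 0.0328. The phosphatase gene Inpp4b (1.12) and the transcription factor gene Hlf (1.39) rose with edgeR adjusted p = 0.0189 and 0.0386. Stab2, a scavenger receptor gene of sinusoidal endothelium, had 0 CPM in the sgNC libraries and 52.0 ± 42.4 CPM (SD, n = 3) in sgRNA. Of 26 interferon gamma response genes 0 rose and 3 fell, and 0 rose and 13 fell adjusted over the list alone (camera adjusted p = 6.42e-19, and 0.53 with an estimated correlation). NK (-0.50) and CD8 T (-0.33) markers were lower and type 2 innate lymphoid markers (0.43) higher by camera with the preset correlation alone. In all 3 genes rose and 18 fell by edgeR and 1 and 11 by DESeq2, and leaving out day 6, 8 or 10 left 226, 6 and 112.

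Regulatory T-like cells lowered Gzmb and Ifitm1 in sgRNA tumours. Gzmb, used by these cells for suppression, fell by 0.84 log2 from 2409 to 1385 CPM, and Ifitm1 by 1.57 log2 (edgeR adjusted p = 0.00928 for each), and these were the only 2 genes past the threshold. The T cell genes Rgs1 (-0.73, adjusted p = 0.0563) and Id2 (-0.75, adjusted p = 0.0939) and the genes Metrnl (-1.03, adjusted p = 0.0960) and Naaa (1.42, adjusted p = 0.0939) followed without passing in edgeR. Ctla4 stood at 842 CPM in each treatment in regulatory T-like cells (-0.01, edgeR adjusted p = 0.993). DESeq2 gave 1 higher and 5 lower genes in regulatory T-like cells, and leaving out day 6, 8 or 10 left 100, 99 and 5 by edgeR.

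In cDC2-like cells of sgRNA tumours ligands of PD-1 and CD28 and some hypoxia genes fell at Leiden resolution 1, and most of these calls were lost at resolution 2. Cd274, which encodes PD-L1, fell from 270 ± 73.1 (SD, n = 3) to 163 ± 22.6 (SD, n = 3) CPM, a log2 fold change of -0.69 (edgeR adjusted p = 0.0467). The gene of the other PD-1 ligand, Pdcd1lg2 (-0.75), and the costimulatory ligand genes Cd86 (-0.93) and Cd80 (-0.82) fell with edgeR adjusted p = 0.0343, 0.0343 and 0.0383. The fusion gene Ocstamp (-2.04), the IL-1 decoy receptor gene Il1r2 (-1.97), the uridine phosphorylase gene Upp1 (-1.74) and Ifitm1 (-1.58) fell with an edgeR adjusted p = 0.00501 for each. Transcripts of Gzma (-1.62) and Gzmb (-1.35), at 0.205% and 0.445% of their top class, also fell (edgeR adjusted p = 0.0287 and 0.0315). The fractalkine receptor gene Cx3cr1 (1.46), the calcitonin receptor modifier gene Ramp1 (1.22), Cd7 (1.09), the transcriptional regulator gene Lmo1 (1.51) and the telomere gene Pot1b (1.13) rose with edgeR adjusted p from 0.0316 to 0.0467. Of 27 hypoxia and glycolysis genes 0 rose and 8 fell, and 0 rose and 21 fell adjusted over the list alone (camera adjusted p = 1.72e-24, and 0.53 with an estimated correlation). Of 8 PD-1 and CD28 ligand and receptor genes 0 rose and 4 fell, and 1 rose and 4 fell adjusted over the list alone (camera adjusted p = 0.000447, and 0.54 with an estimated correlation). Markers of neutrophils (-0.47) and NK cells (-0.59) were lower and of fibroblasts (1.19) and CD8 T cells (0.73) higher in cDC2-like cells by camera with the preset correlation alone. DESeq2 gave 27 higher and 131 lower genes in cDC2-like cells, and leaving out day 6, 8 or 10 left 39, 29 and 725 by edgeR. At resolution 2, where the cDC2 cluster held 1180 in place of 1680 cells and the mature DC cluster 1050 in place of 485, 5 cDC2-like genes passed. Among the genes named here only Ocstamp (-1.76) did, and Cd274 (-0.40, adjusted p = 0.632), Pdcd1lg2 (-0.52, 0.437), Cd86 (-0.61, 0.348) and Cd80 (-0.83, 0.187) did not.

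cDC1-like cells lowered the vitamin D receptor gene Vdr (-2.77), Ifitm1 (-2.46), the epithelial-type surface gene Plet1 (-2.01), the elastase gene Mmp12 (-1.86) and the phosphatidylserine receptor gene Timd4 (-1.85), with edgeR adjusted p from 0.00188 to 0.0395. The replication helicase gene Mcm6 (1.28) and the lectin gene Cd209d (4.49, from 0.886 to 29.1 CPM) rose with edgeR adjusted p = 0.0495 and 0.0349. Neutrophil (-1.08), NK (-0.76) and macrophage (-0.42) markers were lower and fibroblast markers (1.04) higher in cDC1-like cells by camera with the preset correlation alone. In all 3 genes rose and 30 fell in cDC1-like cells (7 and 42 by DESeq2), and leaving out day 6, 8 or 10 left 5, 0 and 128. Mature DC-like cells lowered Mmp13 (-3.69), Mmp12 (-2.46), the glycosyltransferase gene Gcnt1 (-2.29), the apoptotic cell bridging gene Mfge8 (-2.11), the glycolysis gene Aldoc (-2.05) and Gzmb (-1.52), with edgeR adjusted p from 0.00195 to 0.0493. The transporter genes Slco5a1 (2.20) and Slc4a8 (1.78), the chaperone gene Clu (1.97), the sulphation gene Papss2 (1.93) and the interferon-induced gene Epsti1 (1.69) rose with edgeR adjusted p from 0.0285 to 0.0479. Macrophage markers (-0.83) were lower and CD4 T (0.90) and CD8 T (0.75) markers higher in mature DC-like cells by camera with the preset correlation alone. In all 22 genes rose and 38 fell in mature DC-like cells (15 and 31 by DESeq2), and leaving out day 6, 8 or 10 left 27, 121 and 8.

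In plasmacytoid DC-like cells the antibody gene Jchain (-7.09), the B cell gene Cd79a (-5.75), Ccl24 (-3.96), Mmp13 (-3.70) and Osm (-3.40) fell. Their edgeR adjusted p ran from 0.000280 to 0.0428, and Fabp4 rose (4.88, adjusted p = 0.0498). Jchain and Cd79a fell beside markers of plasma cells (median -0.32), neutrophils (-1.57), monocytes (-1.52) and macrophages (-1.45) and a rise of CD4 T markers (1.02) by camera, of which 0 passed with an estimated correlation. In all 1 gene rose and 35 fell (0 and 44 by DESeq2), and leaving out day 6, 8 or 10 left 75, 475 and 1. The sgNC cells of day 6 had a median of 3683 UMIs against 7833.5 to 11074 elsewhere, and their library correlated with its pair at 0.0633, the lowest of 42. At resolution 2 Jchain no longer passed (-2.35, adjusted p = 0.206). A cluster led by Igha, Jchain and Cd79a was then 68.0% from sgNC day 6, so stray cells stay open.

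In cluster 2, the myeloid group with Mmp12, Nos2 and Vegfa, Mmp13 and some antiviral genes fell in sgRNA tumours. Mmp13 fell from 1281 ± 112 (SD, n = 3) to 433 ± 109 (SD, n = 3) CPM, a log2 fold change of -1.59 (edgeR adjusted p = 0.00834). The angiogenic factor gene Pgf (-1.71), the prostaglandin synthase gene Hpgds (-1.66), the respiratory chain gene Cox4i2 (-1.55) and the growth factor gene Tgfb3 (-1.51) fell with edgeR adjusted p from 0.00846 to 0.0191. The complement gene C1s1 (2.19), the lysozyme gene Lyz1 (1.63), Il12a (1.60), which encodes a chain of IL-12, the leukotriene synthase gene Ltc4s (1.39) and Tmeff1 (1.16) rose with edgeR adjusted p from 0.00846 to 0.0298. The antiviral genes Rsad2 (-1.15), Ifit2 (-1.19), Ifit1 (-1.04) and Cmpk2 (-1.25) fell with edgeR adjusted p from 0.00846 to 0.0468. Macrophage (-0.43) and endothelial (-0.29) markers were lower and monocyte (0.33) and fibroblast (0.78) markers higher in cluster 2 by camera with the preset correlation alone. DESeq2 gave 79 higher and 118 lower genes in cluster 2, and leaving out day 6, 8 or 10 left 32, 290 and 122 by edgeR.

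Monocyte-like cells of sgRNA tumours raised the lipase gene Lpl (2.27), Retnla (2.68), a mark of alternative activation, and Trerf1 (1.39), with edgeR adjusted p from 0.0227 to 0.0396. The neutrophil chemokine receptor gene Cxcr2 (-2.11), Mmp13 (-1.72), Il1r2 (-1.48), the glycoprotein gene Lrg1 (-1.48) and Ccl24 (-1.28) fell with edgeR adjusted p from 0.0227 to 0.0396. Lpl (4.89%), Cxcr2 (2.36%) and Il1r2 (3.96%) stood at under 5% of their top class. Neutrophil markers (-0.67) were lower while fibroblast markers (0.91) were higher by camera with the preset correlation alone. In all 3 genes rose and 6 fell by edgeR, with 2112 at unadjusted p under 0.05, against 43 and 200 by DESeq2, and leaving out day 6, 8 or 10 left 36, 98 and 7. In neutrophil-like cells the granule gene Ngp fell (-6.87, from 261 ± 258 to 1.59 ± 0.59 CPM, SD, n = 3). Mmp13 (-2.08), Gzmc (-2.15), the maturation gene Cd177 (-1.33) and the granule gene Camp (-5.38), named after its value was seen, fell too. The edgeR adjusted p ran from 0.00522 to 0.0299, and Fabp4 rose (3.59, adjusted p = 0.00305). In all 1 gene rose and 5 fell (1 and 2 by DESeq2), 3 of the 6, with Fabp4, at under 5% of their top class. Leaving out day 6, 8 or 10 left 3, 3 and 118.

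In macrophage-like cells 0 genes passed in edgeR, with 1586 at unadjusted p under 0.05, while DESeq2 gave 62 higher and 61 lower. Leaving out day 10 alone gave 422 macrophage-like genes by edgeR. The lipase gene Lpl had the smallest p in macrophage-like cells (1.88, adjusted p = 0.0636), followed by Gzmg (-4.76, adjusted p = 0.215), Gzmf (-2.81, adjusted p = 0.234) and Il12a (2.57, adjusted p = 0.255) in edgeR. In fibroblast or pericyte-like cells 0 genes passed in edgeR, with 1540 at unadjusted p under 0.05, while DESeq2 gave 92 higher and 48 lower and leaving out day 10 gave 106 by edgeR. The metalloprotease-like gene Adam23 (2.23, adjusted p = 0.109), the potassium channel gene Kcnk10 (-6.23, adjusted p = 0.109), Rgs7bp (-2.70, adjusted p = 0.109) and the glutathione transferase gene Gstm1 (1.61, adjusted p = 0.114) had the smallest p in edgeR in fibroblast or pericyte-like cells.

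Across classes, the lists that fell most widely were cytotoxic effector, hypoxia and glycolysis, and granulocytic suppressor genes, each lower in all 14 classes by camera with the preset correlation. Inflammatory cytokine and chemokine genes were lower in 10 classes and higher in 1, alternative macrophage activation and inhibitory receptor genes lower in 9, and unfolded protein response genes lower in 8. Type I interferon genes were higher in 2 classes, CD8 T-like and CD4 T-like cells, and lower in 7, and interferon gamma response genes were higher in 1, cluster 2, and lower in 6. MHC class I presentation genes were higher in 5 classes and lower in 1, MHC class II genes higher in 3 and lower in 2, and naive and memory T cell genes higher in 5 and lower in 0. Oxidative phosphorylation genes were higher in 1 class and lower in 6, S phase genes higher in 4 and lower in 3, and G2 and M phase genes higher in 2 and lower in 5. Lipid-associated macrophage genes were higher in 1 class and lower in 5, immediate early and dissociation stress genes lower in 5, and PD-1 and CD28 ligand and receptor genes lower in 4. Activation and costimulation genes were lower in 2 classes, apoptosis and p53 genes higher in 1 and lower in 2, and mitochondrially encoded genes higher in 0 and lower in 0. Of 294 pairs of list and class, 26 were higher and 126 lower with the preset correlation, and 0 passed with an estimated correlation, with adjusted p from 0.53 to 0.84. Among the 152 pairs past the threshold with the preset correlation, neutrophil-like lipid-associated macrophage genes were the only pair whose test (higher) and median log2 fold change (-0.0047) had opposite signs. Another split of the 6 libraries gave 150 list calls against the real 152.

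**Figure D4:**
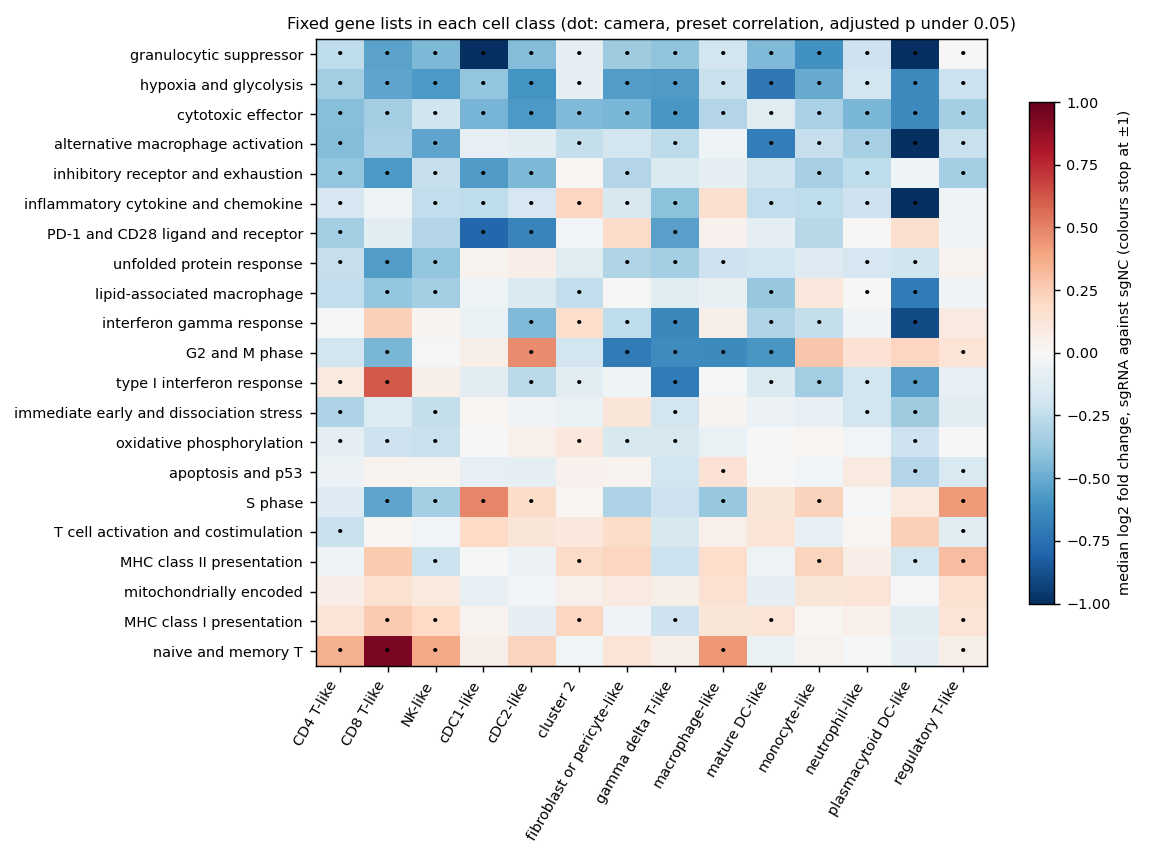
Direction and median log2 fold change of each gene list in each cell class between sgRNA and sgNC tumours.

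Cell-type marker lists moved as well: of 193 pairs 34 were higher and 38 lower by camera with the preset correlation. With an estimated correlation, again on 2 residual degrees of freedom, 0 passed (those 72 at adjusted p from 0.61 to 0.72). Fibroblast markers were higher in all 10 classes tested, CD4 T markers higher in 5 and lower in 0 of 13, and monocyte markers higher in 5 and lower in 1 of 13. Macrophage and NK markers were each lower in 8 of 13 classes and neutrophil markers lower in 7 of 12. CD8 T markers were higher in 5 and lower in 2 of 13, regulatory T markers lower in 3 of 13, epithelial markers higher in 2 of 12, and markers of cDC2 higher in 2 and lower in 1 of 12. Type 2 innate lymphoid markers were higher in 1 and lower in 2 of 12 classes, B cell markers higher in 2 and lower in 1 of 3, cDC1 markers higher in 1 and lower in 1 of 11, and plasmacytoid DC markers higher in 1 of 12. Endothelial (4 classes), mast or basophil (4), mature DC (13) and plasma cell (7) markers were each lower in 1 class and gamma delta T markers changed in 0 of 3.

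Cd28 itself did not pass in any of the 14 classes tested, with log2 fold changes from -0.12 to 1.08, of which 12 were positive. In edgeR Pdcd1 fell in 2 of 11 classes, CD4 and CD8 T-like cells. Cd274, Cd80 and Cd86 each fell in 1, cDC2-like cells, but did not pass at resolution 2. Ctla4 fell in 1 of 13 classes, CD4 T-like cells, and without day 6 also in NK-like and gamma delta T-like cells (adjusted p = 0.00823 and 0.0187), and Prf1 in 1 of 12, NK-like cells, with Prf1 negative in all 12. Ifng did not pass in any of 13 classes, with log2 fold changes from -0.39 to 0.82.

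Cd28 and Pdcd1 RNA was found in some epithelial or tumour-like cells (Krt8 in 93.5%), more often than in monocyte-like cells (Pdcd1 7.49% and 0.491%). A Cd28 molecule was found in 12.2% (10.8 to 13.6, exact binomial interval, counting error only) of 2162 epithelial or tumour-like cells at a median of 24575 molecules per cell, in 18.6% of fibroblast or pericyte-like cells (17558), in 3.37% of macrophage-like (12022), 1.32% of monocyte-like (8501.5) and 85.6% of CD4 T-like cells (5396). Thinned to 3000 molecules per cell, the Cd28 shares were 3.04% (2.30 to 3.93) of epithelial or tumour-like, 6.33% of fibroblast or pericyte-like, 1.07% of macrophage-like, 0.467% (0.3235 to 0.652) of monocyte-like and 72.7% of CD4 T-like cells. The leukocyte gene Ptprc, so thinned, was in 19.1% of epithelial or tumour-like and 98.2% of CD4 T-like cells. Free RNA alike in all cells does not give the Cd28 difference, but Pdcd1 shared it, and doublets with leukocytes, untested, stay open. In sgNC and sgRNA epithelial or tumour-like cells Cd28 was in 12.9% and 11.5% (12.55 and 6.98 CPM). Cd274 was in 52.0% and 70.4% (63.6 and 79.3). Median depths were 20106 and 31820. Day 6 gave 28 of 1080 sgNC and 576 of 1082 sgRNA cells, so the treatments differ in day. Tumour cells reached a CD45+ sort only by escape, so these values do not describe them at large.

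Over days 6 to 10 the mast or basophil-like cluster led by Mcpt8 almost disappeared. It held 678, 14 and 16 cells in sgNC and 420, 7 and 6 in sgRNA. The cluster led by Mcpt1 held 9, 24 and 4, and 4, 7 and 3. DESeq2 called most genes in macrophage-like cells (644 rising and 775 falling). Mast or basophil-like cells were 6.14% and 4.29% of the sgNC and sgRNA libraries on day 6, 0.287% and 0.160% on day 8, and 0.187% and 0.0995% on day 10. Their slope was -1.33 log2 per day (edgeR adjusted p = 0.00866), the only 1 of 17 classes past the threshold, with 2 at unadjusted p under 0.05. Without the sgRNA library of day 6 this slope was -1.14 with an edgeR adjusted p = 0.158. CD8 T-like cells had a slope of 0.76 log2 per day (edgeR adjusted p = 0.135), which passed without the sgNC library of day 8 (adjusted p = 0.0341). Of the gene slopes, 839 rose and 1497 fell by edgeR and 1943 rose and 2986 fell by DESeq2, and leaving out 1 library gave 81 to 2816 in edgeR. Of the slopes named below, 56 no longer passed without the sgRNA and 44 without the sgNC library of day 6, and 61 without the sgNC library of day 10. CD4 T-like cells held 252 rising and 575 falling genes, NK-like cells 215 and 324, neutrophil-like cells 160 and 177, macrophage-like cells 63 and 118, fibroblast or pericyte-like cells 48 and 69, monocyte-like cells 32 and 65, and gamma delta T-like cells 16 and 88. Cluster 2 held 32 and 43, cDC2-like cells 15 and 28, regulatory T-like cells 5 and 7, and mature DC-like cells 1 and 3. In CD8 T-like, cDC1-like and plasmacytoid DC-like cells 0 genes passed in edgeR, with 703, 1053 and 776 at unadjusted p under 0.05, and DESeq2 gave 12 and 3, 20 and 47, and 12 and 9 rising and falling.

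Leading genes of the Mcpt8 cluster were among the named falling genes of other classes. No gene list was tested over days. In CD4 T-like cells Gata2 (-2.20 log2 per day), Il6 (-1.75), Il17f (-1.35) and Fcmr (-1.30) fell and Samd3 (0.67), Olfr530 (0.63), Mapt (0.62) and Vmn2r84 (0.56) rose by edgeR. In NK-like cells the eotaxin gene Ccl24 (-1.14), the monocyte attractant gene Ccl2 (-0.97), Cyp11a1 (-1.59) and the histone gene Hist1h2ad (-1.06) fell. Ctsg (1.14, in sgNC alone, and at most 0.755 CPM in sgRNA), Slc17a6 (1.05), Eps8l3 (0.93) and Irx3 (0.79) rose. In gamma delta T-like cells the mitosis genes Bub1 (-2.00), Aurkb (-1.64) and Cenpe (-1.30) and Ccl24 (-1.76) fell and Bmp2 (0.67), Zfp946 (0.65), Klrc2 (0.60) and B3gat3 (0.41) rose. In neutrophil-like cells Gata2 (-1.87), Cyp11a1 (-1.69), Mcpt8 (-1.37) and Il13 (-1.35) fell and Gpnmb (1.03), Prok2 (0.83), the hypoxia gene Hilpda (0.73) and Phldb2 (0.69) rose. In macrophage-like cells Ms4a3 (-3.16), Grm6 (-2.53), Mcpt8 (-1.62) and Ms4a2 (-1.61) fell and the resident macrophage gene Vsig4 (1.63), Cav1 (1.04), Tmeff1 (0.77) and Gpr162 (0.74) rose. In monocyte-like cells Gata2 (-1.71), Cyp11a1 (-1.59), Ankrd55 (-1.48) and Msx3 (-1.43) fell and Carmil1 (0.84), Kit (0.74), Ptgfrn (0.68) and Thbs1 (0.64) rose. In cluster 2 the chemokine gene Ccl17 (-2.25), Tmem215 (-1.87), Mcpt8 (-1.69) and Cyp11a1 (-1.61) fell and Cav1 (0.82), Tmeff1 (0.81), Cav2 (0.70) and Pid1 (0.62) rose.

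In fibroblast or pericyte-like cells the interferon-induced genes Cxcl9 (-0.85), Ubd (-0.85), Gbp10 (-0.84) and Sectm1b (-1.14) fell per day and Agtr2 (1.34), the TAM ligand gene Gas6 (1.05), Smoc2 (0.96) and the imprinted gene H19 (0.92) rose by edgeR. In cDC2-like cells Rnase2a (-1.22), Plet1 (-0.80), Ccl24 (-0.80) and Tnp2 (-0.72) fell and Fcrls (0.88), the fibronectin gene Fn1 (0.61), Pde3b (0.40) and Dock5 (0.34) rose. In mature DC-like cells the sterol gene Fdps (-1.07), Mfge8 (-0.76) and Fabp5 (-0.42) fell and Cd81 (0.63) rose. In regulatory T-like cells Gzma (-0.53), Ccl6 (-0.42), Ltb4r1 (-0.40) and Fcer1g (-0.38) fell and Bmyc (0.41), the activation gene Nr4a3 (0.40), Rln3 (0.34) and Zfp36l1 (0.22) rose. In the classes named, Gata2, Cyp11a1, Mcpt8, Ms4a2, Grm6 and Il6, Il13 in neutrophil-like, Cav1 in macrophage-like and Gzma and Ccl6 in regulatory T-like cells were at under 1% of their level in the top class.

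The difference between treatments changed over the days for 9 genes, all lower per day in sgRNA relative to sgNC by edgeR, with 6408 at unadjusted p under 0.05. In gamma delta T-like cells the T cell attractant gene Cxcl10 stayed between 460 and 572 CPM in sgNC and went from 476 on day 6 to 90.1 on day 8 and 31.7 on day 10 in sgRNA, a change of -0.998 log2 per day (edgeR adjusted p = 0.00174). Tnfrsf9 in gamma delta T-like cells went from 302 to 566 and 633 CPM in sgNC and from 200 to 105 and 54.6 CPM in sgRNA (-0.73, edgeR adjusted p = 0.0325). Of the 17 class shares 0 passed for this difference per day in edgeR, and 0 had an unadjusted p under 0.05.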

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

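The test of CD4 T-like cells against the other lymphoid cells was chosen after its result had been seen. The alternatives without cycling clusters and without cells holding Mki67 or Top2a were chosen after the data had been seen but before their own values, and quartiles as their spread after these. The other tests were written down before their values were known.

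A treatment difference that moved with the day, by a test of treatment by day in edgeR, was found for 9 genes in 3 classes. In gamma delta T-like cells the difference fell per day for Cxcl10 (-0.998 log2), Tnfrsf9 (-0.733), the cell cycle inhibitor gene Cdkn1a (-0.780) and Il1rl1 (-0.765), which encodes the IL-33 receptor, with edgeR adjusted p from 0.00174 to 0.0395. Il1rl1 stood at 24.1 CPM in sgNC and 282 in sgRNA on day 6 and at 240 and 351 on day 10, so sgNC approached sgRNA. Cdkn1a stood at 63.0 and 140 CPM on day 6 and at 139.5 and 35.3 on day 10, a change of sign.

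In fibroblast or pericyte-like cells the acute phase gene Lbp (-1.471), the pentraxin gene Ptx3 (-1.962), the adhesion gene Chl1 (-1.528) and the predicted gene Gm18787 (-2.157) had a difference that fell per day, with edgeR adjusted p from 0.0199 to 0.0389. Lbp stood at 15.4 CPM in sgNC and 833 in sgRNA on day 6, 136 and 1025 on day 8, and 1276 and 1189 on day 10. Ptx3 went from 2.80 to 27.9 and 306 CPM in sgNC and from 184 to 81.8 and 93.9 CPM in sgRNA. Chl1 stood at 7.002 and 303 CPM on day 6 and at 660.5 and 340 on day 10, and Gm18787 at 0 and 46.5 and at 74.2 and 27.8, so Ptx3, Chl1 and Gm18787 changed sign by day 10. The 101 fibroblast or pericyte-like cells of sgNC on day 6 stood apart, with a median of 1711 UMIs and 1076 genes per cell against 22400.5 and 5006 in sgRNA on that day and 12134.5 to 27822 UMIs in the other 4 libraries. In cluster 2 the metallothionein gene Mt2 changed by -0.892 log2 per day (edgeR adjusted p = 0.0319), from 115 and 412 CPM on day 6 to 376 and 114 on day 10. Each value rests on 1 library per treatment and day, and for these 9 genes no biological or technical explanation was tested.

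The fall of the same genes in many classes was weighed first. Of the genes called within classes 50 were lower in 3 or more classes, among them Mmp13, Gzmb, Ifitm1, Gzmc and Spp1. If free RNA of other cells were the whole source, most of these pairs of gene and class would lie under 5% of the level in the top class, and 26.46% did (50 of 189), between the bounds set beforehand. Free RNA may therefore account for part of the pattern, such as Gzmc in neutrophil-like and Mmp13 in plasmacytoid DC-like cells, and the design leaves the rest open. A lower level of these transcripts in the whole suspension of sgRNA tumours and a change inside each class cannot be told apart for those 50 pairs, since empty droplets were not at hand.

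The fall of granzymes in CD8 T-like cells was weighed second. Free RNA would put Gzmc, Gzmd, Gzme and Gzmf at about the same UMIs per cell in CD8 T-like as in monocyte-like cells of sgNC, whereas the ratio was 342.5, 168.7 and 127.7 on days 6, 8 and 10, which argues against free RNA as the source. Fewer cells in the cycling clusters would have shrunk the changes once these clusters were left out, yet the median size over the 156 genes kept 99.19% of its value (1.451 and 1.439 log2, quartiles over genes 94.37% and 104.1%), with all 156 of the same sign. The remaining CD8 T-like cluster still held Mki67 or Top2a in 33.07% of cells. Without every cell holding either gene, which left as few as 47 cells in a library, the median size over those of the 156 genes still tested kept 82.74% (1.435 and 1.188 log2, quartiles 71.06% and 99.32%), with each of the same sign and 101 past the threshold. Fewer cycling cells as the whole cause are thus argued against, while a part in the size of the changes stays open, as the quartiles reach under the bound of 80% set beforehand. Reads shared between these near-identical granzymes stay open as to which of them changed. A hypothesis is that CD8 T-like cells of sgRNA tumours were less far along towards terminal effector and exhausted states, as the fall of Pdcd1 and Entpd1 and the rise of Tcf7 and Slamf6 may reflect, while the rise of Klrg1 goes against it, and this was not tested. A shift between clusters of the class and a change inside them stay open; cycling clusters held 17.9% of CD8 T-like cells in sgNC and 8.58% in sgRNA, cells with Mki67 or Top2a were 51.9% and 30.9%, and without day 6 there were 4 genes past the threshold.

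The larger CD4 T-like share was weighed last. A loss of macrophage-like cells would raise every other share alike and not move the ratio of CD4 T-like to other lymphoid cells. Its log2 was higher in sgRNA by 0.740, 1.51 and 0.931 on days 6, 8 and 10 (mean 1.061 ± 0.401, SD, n = 3). This argues against loss of a non-lymphoid class as the whole cause. Loss of other lymphoid cells, which would raise this ratio, loss in digestion or sorting, or a difference between tumours was untested and stays open. The share did not pass in edgeR (adjusted p = 0.245).

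The 6 libraries can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. The real division gave 1151 genes and the highest other 71, with 1 of 10 as large, the real one itself. The days pair the libraries, and among the 4 divisions that part all 3 days the highest other was 5. By class the real and highest other counts were 219 and 1 for CD4 T-like, 156 and 0 for CD8 T-like, 264 and 0 for NK-like, 33 and 5 for cDC1-like, 136 and 0 for cDC2-like, 209 and 0 for cluster 2, 21 and 10 for gamma delta T-like, 60 and 3 for mature DC-like, 36 and 24 for plasmacytoid DC-like, and 2 and 0 for regulatory T-like cells, each with 1 of 10 as large. In macrophage-like and fibroblast or pericyte-like cells the real count was 0 and all 10 were as large (edgeR; 1586 and 1540 genes at unadjusted p under 0.05, 123 and 140 by DESeq2). In monocyte-like cells another division gave 26 against the real 9 and in neutrophil-like cells 62 against 6, with 3 of 10 as large in each. With day as a block, a division that does not part all days compares only the sgRNA and sgNC libraries of 1 day. Such a division therefore cannot show a structure of the samples other than treatment. The highest among divisions parting all days were 0 and 1. For gene lists the real division gave 152 calls and the highest other 150 (143 among those parting all days).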

How the results depend on the processing

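The alternatives of an estimated correlation for marker lists, without cycling clusters, without CD8 T-like cells holding Mki67 or Top2a, with immune classes alone as the denominator and without unnamed clusters were chosen after the data had been seen, and the others before. Where a result below changed, the cause was not tested. Of the gene values given for treatment, 247 kept direction and side of the threshold and 4 no longer passed with under 5% mitochondrial UMIs, 244 and 4 with at least 500 genes, 249 and 2 with DESeq2 size factors, 246 and 2 without cycling clusters, 230 and 15 with doublets kept, 188 and 24 by DESeq2, 184 and 40 with equal numbers of cells, 180 and 36 at Leiden resolution 2, 213 and 0 with no filter on low counts, 159 and 0 without genes under 5% of their top class, and 157 and 63, 174 and 40 and 179 and 43 without day 6, 8 and 10. Genes newly passing numbered 37 with no filter, 15 by DESeq2, 7 each with equal numbers of cells and at resolution 2, 11, 9 and 13 without day 6, 8 and 10, and 0 to 3 otherwise. Each named gene called with all days kept its direction wherever tested. Naming by the same sign on all days nearly fixed this for days left out. Only genes named whatever their values reversed.

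The block mattered most. With no replicate block, 110 named genes kept their side of the threshold and 128 no longer passed, and the genes past it fell from 1151 to 25 (8 higher and 17 lower), with 21 in CD8 T-like, 3 in gamma delta T-like and 1 in monocyte-like cells and 0 in CD4 T-like, NK-like, cDC1-like, cDC2-like, cluster 2, mature DC-like, neutrophil-like, plasmacytoid DC-like and regulatory T-like cells by edgeR (by DESeq2 with the block 187, 103, 49, 158, 197, 46, 3, 44 and 6, and by edgeR with the block at unadjusted p under 0.05 from 713 to 2191). Without the block Cd28 (-0.0411) and Cd80 (-0.0201) in cluster 2, Cd86 in neutrophil-like cells (-0.00763) and the mature DC-like share (-0.245) changed sign, each with an edgeR adjusted p over 0.8.

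Gene counts moved over 1.5 times as follows. The DESeq2 test gave 103 in NK-like (264 by edgeR), 140 in fibroblast or pericyte-like (0), 12 in gamma delta T-like (21), 123 in macrophage-like (0), 243 in monocyte-like (9), 3 in neutrophil-like (6) and 6 in regulatory T-like cells (2), and 4929 slopes per day (1943 higher and 2986 lower). DESeq2 size factors gave 42 in gamma delta T-like and 58 in plasmacytoid DC-like cells. Leiden resolution 2 gave 85 in CD4 T-like (219), 5 in cDC2-like (136), 23 in fibroblast or pericyte-like, 78 in gamma delta T-like, 115 in mature DC-like (60), 19 in monocyte-like and 73 in plasmacytoid DC-like cells (36). Under 5% mitochondrial UMIs gave 4 in regulatory T-like cells, and at least 500 genes gave 4 there and 11 in neutrophil-like cells. Without cycling clusters there were 431 in CD4 T-like, 289 in CD8 T-like (156), 41 in gamma delta T-like and 4 in regulatory T-like cells, and without cells holding Mki67 or Top2a 199 in CD8 T-like cells, within 1.5 times. With doublets kept there were 102 in CD8 T-like, 257 in plasmacytoid DC-like cells and 1 in regulatory T-like cells.

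Equal numbers of cells per library gave 145 in CD4 T-like, 9 in cDC1-like (33), 71 in cDC2-like, 54 in cluster 2 (209), 3 in mature DC-like, 5 in monocyte-like, 82 in plasmacytoid DC-like and 13 in regulatory T-like cells. Without genes under 5% of their top class there were 53 in cDC1-like, 49 in gamma delta T-like, 3 in neutrophil-like and 102 in plasmacytoid DC-like cells. With no filter on low counts there were 7142 in all (2980 higher and 4162 lower): 980 in CD4 T-like, 798 in CD8 T-like, 745 in NK-like, 282 in cDC1-like, 769 in cDC2-like, 780 in cluster 2, 862 in fibroblast or pericyte-like, 169 in gamma delta T-like, 88 in macrophage-like, 297 in mature DC-like, 611 in monocyte-like, 148 in neutrophil-like, 431 in plasmacytoid DC-like and 182 in regulatory T-like cells, and 11319 slopes (4703 higher and 6616 lower). Gene lists past the threshold went from 152 to 0 and marker lists from 72 to 0 with an estimated correlation, and gene lists stayed within 1.5 times without the block or any day.

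Leaving out 1 day at a time gave 1164 to 2506 genes (405 to 1138 higher and 759 to 1368 lower): 34 to 428 in CD4 T-like, 4 to 669 in CD8 T-like, 49 to 577 in NK-like, 0 to 128 in cDC1-like (0 without day 8, against 33 by edgeR and 49 by DESeq2 with all days and 922 at unadjusted p under 0.05), 29 to 725 in cDC2-like, 32 to 290 in cluster 2, 6 to 226 in gamma delta T-like, 8 to 121 in mature DC-like, 7 to 98 in monocyte-like, 3 to 118 in neutrophil-like, 1 to 475 in plasmacytoid DC-like, 5 to 100 in regulatory T-like, 0 to 106 in fibroblast or pericyte-like and 0 to 422 in macrophage-like cells. Leaving out 1 library gave 81 to 2816 slopes (15 to 1013 higher and 66 to 1803 lower). The fewest, 81, came without the sgRNA library of day 6, where 6 named slopes passed and 56 no longer did; without the sgNC libraries of days 6, 8 and 10 these were 19 and 44, 70 and 12 and 17 and 61, and without the sgRNA libraries of days 8 and 10 62 and 21 and 52 and 28. A lone library of a day was assumed to vary like the others.

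Among the shares, CD4 T-like cells passed with immune classes alone as the denominator (1.29, edgeR adjusted p = 0.0430), 1 of 17 against 0, and not under the other alternatives (edgeR adjusted p from 0.0739 to 0.674). Some shares changed sign. The gamma delta T-like share (0.0335) went to -0.294 with TMM factors over classes, -0.0413 without neutrophils and -0.0207 without unnamed clusters, and from -0.248 to 0.275 over days left out. The mature DC-like share (0.0243) went to -0.460 at Leiden resolution 2, -0.281 with TMM factors, -0.0475 without neutrophils and -0.0279 without unnamed clusters, and from -0.521 to 0.596 over days left out. Over days left out cluster 2 went from -0.963 to 0.511, epithelial or tumour-like cells (0.388 with all days) from -1.16 to 2.17, NK-like cells from -0.367 to 0.144 and plasmacytoid DC-like cells (0.4765) from -0.0224 to 1.005.

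Slopes of shares past the threshold numbered 0 to 2 when 1 library was left out, 0 without the sgRNA library of day 6 in edgeR (1 with all libraries, 2 at unadjusted p under 0.05). With 1 library left out the mast or basophil-like slope went from -1.52 to -1.14 and the CD8 T-like slope from 0.561 to 0.959. Slopes that changed sign were cDC2-like (-0.215 to 0.149), cluster 2 (-0.0901 to 0.613, 0.261 with all libraries), endothelial-like (-0.109 to 0.478, 0.215 with all), epithelial or tumour-like (-0.685 to 0.515), fibroblast or pericyte-like (-0.329 to 0.2496), monocyte-like (-0.140 to 0.152), neutrophil-like (-0.0935 to 0.1097), NK-like (-0.0857 to 0.0331), plasmacytoid DC-like (-0.271 to 0.0618) and regulatory T-like cells (-0.0516 to 0.2305). At Leiden resolution 2 the slopes of cDC2-like (0.105), fibroblast or pericyte-like (0.0315), monocyte-like (-0.0834) and NK-like cells (0.0482) changed sign, and with at least 500 genes that of monocyte-like cells (-0.00169).

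Genes named whatever their values changed sign, some far from 0 with all days: Pdcd1 (-0.6665) and Ifng (0.648) in fibroblast or pericyte-like, Ctla4 in gamma delta T-like (-0.600) and NK-like (-0.352) and Cd28 in mature DC-like cells (0.579). Of these only Ctla4 in NK-like and gamma delta T-like cells passed anywhere, without day 6 (adjusted p = 0.00823 and 0.0187). The sign changes were, by DESeq2, Ctla4 in neutrophil-like (-0.0446) and Cd86 in regulatory T-like cells (0.162), with DESeq2 size factors Cd28 in cluster 2 (-0.00225), and with under 5% mitochondrial UMIs Cd86 in regulatory T-like cells (0.0352). At Leiden resolution 2 they were Ifng in NK-like (0.00307) and monocyte-like (-0.0487), Cd80 in mature DC-like (0.0579) and Ctla4 in regulatory T-like cells (0.00288). With at least 500 genes they were Cd28 in cluster 2 (-7.14e-05) and Ctla4 in neutrophil-like cells (-0.0639), and without cycling clusters Cd28 in regulatory T-like cells (0.0130). With doublets kept they were Ifng in CD8 T-like (0.350), cDC1-like (0.00656) and plasmacytoid DC-like (0.0488), Ctla4 in neutrophil-like (-0.0877) and regulatory T-like (0.0325) and Cd86 in neutrophil-like cells (-0.0429). With equal numbers of cells they were Ifng in NK-like (0.00981) and regulatory T-like (-0.00461), Cd80 (-0.201) and Cd274 (0.0265) in cluster 2 and Ctla4 in regulatory T-like cells (0.0498). With no filter they were Cd28 in cluster 2 (-0.0184) and Ctla4 in neutrophil-like (-0.00783) and regulatory T-like cells (0.00557).

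Over days left out the log2 fold change of Ifng went from -0.917 to 0.457 in CD8 T-like, -0.144 to 0.0673 in NK-like, -0.984 to 1.776 in fibroblast or pericyte-like, -9.84e-05 to 0.316 in monocyte-like, -0.247 to 0.218 in neutrophil-like and -0.0571 to 0.375 in regulatory T-like cells. Cd274 went from -0.0270 to 0.136 in CD8 T-like, -0.0824 to 0.0164 in cluster 2, -0.703 to 0.0165 in fibroblast or pericyte-like, -0.156 to 0.0457 in macrophage-like, -0.222 to 0.00579 in mature DC-like and -0.0577 to 0.0336 in neutrophil-like cells. Ctla4 went from -0.935 to 0.0361 in NK-like, -0.218 to 0.277 in cluster 2, -1.524 to 0.158 in gamma delta T-like, -0.0222 to 0.466 in macrophage-like, -0.197 to 0.223 in neutrophil-like and -0.145 to 0.0618 in regulatory T-like cells. Cd28 went from -0.216 to -0.0375 in cluster 2 (0.000555 with all days), -0.5575 to 0.1715 in gamma delta T-like, -0.5025 to 0.5595 in mature DC-like, -0.0421 to 0.326 in plasmacytoid DC-like and -0.118 to 0.0292 in regulatory T-like cells. Pdcd1 went from -0.999 to 0.0137 in fibroblast or pericyte-like and -0.199 to 0.577 in mature DC-like cells, and was 0.0302 in monocyte-like cells without day 8, the only such fit that kept the gene. Cd86 went from -0.769 to 0.346 in fibroblast or pericyte-like, -0.0827 to 0.124 in neutrophil-like and -0.486 to 0.8145 in regulatory T-like cells, Cd80 from -0.191 to 0.219 in mature DC-like cells, and Prf1 from 0.0285 to 1.024 in plasmacytoid DC-like cells (-0.206 with all days).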

Other observations

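Fabp4, an abundant gene of capillary endothelium and some macrophages, rose in 5 classes of sgRNA tumours, and in each it stood under 5% of its top class. Endothelial-like cells, few in a CD45+ sort, averaged 0.391% of cells in sgNC and 0.855% in sgRNA, and fibroblast markers rose in all 10 classes tested by camera with the preset correlation and in 0 with an estimated one. Stab2, another endothelial gene, was seen in gamma delta T-like cells of sgRNA alone, at 0 CPM in sgNC and 52.0 ± 42.4 CPM (SD, n = 3) in sgRNA.

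Type I interferon genes were higher by camera with the preset correlation in CD8 T-like cells (median 0.611) and CD4 T-like cells (0.0980), and lower in gamma delta T-like (-0.700), plasmacytoid DC-like (-0.546), monocyte-like (-0.349), cDC2-like (-0.272), neutrophil-like (-0.187), mature DC-like (-0.147) and cluster 2 (-0.112) cells. With an estimated correlation 0 of these passed (adjusted p from 0.53 to 0.74), and a test between the classes was not run.

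Cluster 17, left without a name because 63.9% of its barcodes were scored as doublets (median 16565 UMIs), carried Penk, Ccl1, Cxcr6 and Ifng and, with those doublets left out, held 0.35% and 0.20% of sgNC and sgRNA cells on day 6, 1.57% and 2.76% on day 8, and 0.33% and 0.53% on day 10.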
